A study of Mus musculus with 26 samples.

How the data were processed

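Messenger RNA levels were measured on 26 Affymetrix arrays, 1 array per RNA sample, in mouse embryonic stem cells and in epiblast-like cells made from such cells. Per the labels' protocols, all lines were C57BL/6 and male, stem cells grew on mouse embryonic fibroblast feeders, RNA was taken up on RNeasy Micro columns and biotin-labelled cRNA was made by the Affymetrix one-cycle protocol. The arrays fall into 13 groups of 2. Wild-type cells and Prdm14 knockout cells were each grown in 2i medium, in serum with LIF, in serum without LIF and in serum with the MEK inhibitor PD0325901. Knockout cells that carry a transgene for a tagged Prdm14 protein, named AGP14 in the labels, were grown in 2i, serum and serum without LIF. Epiblast-like cells (EpiLC) of day 2 and day 3 came from a line with intact Prdm14 and a pair of reporter transgenes. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical, although stem cell arrays of the same number deviated together across media.

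The deposited table holds 1 log2-scale value per probe set and array, for 45100 probe sets. Image analysis, background correction, normalization and summarisation of these values are not given in the sources used here. Array medians lay between 4.86 and 5.01, 25th percentiles between 3.20 and 3.28 and 95th percentiles between 10.5 and 10.7, so the arrays had been brought to a common scale before they were deposited. The lowest value was exactly 0, held by 361 to 453 probe sets per array, and the highest was 13.89. The base of the logarithm is not stated. Base 2 was inferred from the highest value, which in base 2 lies within the range of a 16-bit scanner and in natural log would lie above it. The hybridization controls cre and bioB do not settle it: they differed by 4.79, nearer to the 4.20 that their nominal ratio would give in natural log than to the 6.06 in base 2. Every log2 difference below therefore rests on an inferred base. The number of arrays per group limits the precision of all values.

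Probe sets were named from the platform annotation of the table. Of the probe sets, 64 were controls, 34944 had 1 gene symbol, 932 had several and were not used, and 9160 were not listed with a gene and stay unnamed here. Each of 18193 genes was given the value of its single-symbol probe set with the highest mean over all arrays; 9010 genes had more than 1 probe set. For 18032 of the genes the symbol was found in the RefSeq gene table of assembly GRCm38.p6, which was used for chromosome neighbours only. Among 274 pairs of a named gene and a comparison, 95 were of genes with further probe sets, and in 23 of these a further probe set had the opposite sign. These include Nt5e with MEK inhibitor (further probe sets -0.40 to 0.54), Prex2 without LIF (-0.14) and, for AGP14 against knockout, Nr5a2 without LIF (-0.65 to 4.65).

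Differences were tested with limma 3.58.1 in R 4.3.3. A single model held 1 coefficient per group over all 26 arrays, left 13 residual degrees of freedom, and was moderated with an intensity trend (prior degrees of freedom 5.05). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Genes described as having risen, fallen or changed passed this limit. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The procedure was run on simulated data for knockout against wild type in serum. It called 18 of 67 genes changed 1.5-fold, 29 of 67 at 2-fold and 57 of 66 at 4-fold. It called 3 unchanged genes, but lines shared across media were not tested.

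Comparisons, gene lists and the rule for named genes were fixed before the data were examined. Prdm14 is named in every group. For knockout against wild type the 8 largest rises and 8 largest falls could be named, and for other comparisons 5 of each, among genes that passed and whose arrays did not overlap between the groups. List members could be named where they were among the 5 with the smallest p of their list, or where a value that did not pass is given. The 25 lists covered naive pluripotency, core pluripotency, primed and epiblast-like genes, DNA methylation, DNA demethylation, FGF ligands and receptors, ERK response and feedback, LIF and STAT3 response, Wnt response, extraembryonic endoderm, mesoderm, neuroectoderm, trophoblast, germline genes silenced by promoter methylation, primordial germ cells, the 2-cell-like state, polycomb complexes, HOX clusters, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle in G2 and M, p53 response, feeder fibroblasts and housekeeping genes. Some genes are in more than 1 list, and not every list that passed is described. Lists were tested with camera in limma at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison. The same test with an estimated correlation is given beside it, as is the number of members called when p-values were adjusted over the list alone. Serum against 2i and LIF withdrawal in AGP14, serum with MEK inhibitor against 2i, and EpiLC day 3 against wild type in 2i were added after seeing the data.

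Spike-in controls split the arrays into 2 labelling batches. The poly-A control lys, which is added to RNA before labelling, lay at 6.93 to 7.49 on 14 arrays and at 13.41 to 13.53 on 12 arrays. The first batch held all arrays in serum and in serum without LIF and those of AGP14 in 2i. The second held wild type and knockout in 2i, both groups with MEK inhibitor, and EpiLC. The 3' minus 5' signal of beta-actin was 0.52 to 0.63 in the first batch and 0.18 to 0.33 in the second. Knockout against wild type lies within a batch in each medium, whereas serum against 2i and MEK inhibitor against serum cross the batches for wild type and knockout.

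The pairing of replicate numbers was checked by correlating deviations from the group means over 9483 genes of mean above 6. Arrays with the same number in different media correlated at 0.483 to 0.779 in wild type (6 pairs of media), 0.468 to 0.739 in knockout (6 pairs) and 0.421 to 0.511 in AGP14 (3 pairs). Between genotypes the correlation was -0.148 to 0.160 (62 pairs), and between the EpiLC days it was 0.003. The numbers thus pair arrays within a genotype, not across, as a repeated line or culture would. The main model has no block for this, so its genotype p-values may be too small. A replicate block was fitted as planned, and the line as fixed columns or a random block (correlation 0.203) after seeing the data.

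Further alternatives were quantile normalization of the deposited values, the mean of a gene's probe sets, no intensity trend, a model of the arrays of the compared groups alone, removal of genes below the 40th percentile of mean level (10916 genes left), and removal of each of the 26 arrays in turn. A different pseudocount was not run, because the values are already on a log scale. For the signature in 2i and the AGP14 covariances, unchanged groups were simulated against the shared arrays, 100 times. Because wild-type and knockout arrays of the same number deviate together across media, overlaps, shares of turned genes and the EpiLC signature were also computed with different replicate numbers on both sides, a lone array being assumed to vary like the other groups; this was added after seeing the data. Chance overlap of independent lists was taken as the product of their sizes over the number of genes.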

Results

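The study profiled gene expression in mouse embryonic stem cells with and without Prdm14, a PR-domain protein of naive pluripotent cells and primordial germ cells, in 4 media that differ in their signalling inputs. The 2i medium was N2B27 with the MEK inhibitor PD0325901 (0.4 uM), the GSK3 inhibitor CHIR99021 (3 uM) and LIF (1000 units per ml). The serum medium held 20% fetal bovine serum and LIF for 2 days, and was also used without LIF or with PD0325901 added. Each of the 13 groups had 2 arrays. Values are log2 signals as deposited, differences are log2 differences with their standard error (SE), and the groups are named by their labels.

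The Prdm14 probe set did not follow the genotype labels in every medium. In 2i it lay at 9.18 ± 0.32 (SD, n = 2) in wild type and 11.28 ± 0.06 in the arrays labelled knockout, a rise of 2.11 (SE 0.41, adjusted p = 0.00268). With MEK inhibitor it lay at 9.26 ± 0.31 and 10.74 ± 0.19, a difference of 1.48 (adjusted p = 0.049) whose call was lost when any 1 of the 4 arrays was left out. In serum it was 6.63 ± 1.06 in wild type and 5.94 ± 0.76 in the arrays labelled knockout, a difference of -0.70 that did not pass (adjusted p = 0.389). Without LIF the values were 4.73 ± 0.63 and 3.63 ± 0.59, a difference of -1.10 that did not pass either (adjusted p = 0.153). AGP14 arrays lay at 9.21 ± 0.13 in 2i, 6.38 ± 0.06 in serum and 4.99 ± 0.18 without LIF, and differed from wild type by 0.03, -0.26 and 0.27, none of which passed. Against the arrays labelled knockout they differed by -2.08 in 2i, across labelling batches (adjusted p = 0.0010), by 0.44 in serum, which did not pass (adjusted p = 0.593), and by 1.36 without LIF (adjusted p = 0.0326). The last call was lost without AGP14 replicate 1 (0.177) or 2 (0.0943) or knockout replicate 1 (0.288), without the intensity trend (0.0634) and in a model of the 4 arrays alone (0.0507). Whether the probe set detects the transgene is not given in the sources used here. EpiLC had the lowest levels, 3.07 ± 0.19 on day 2 and 2.91 ± 0.30 on day 3. A probe outside the deleted part of a gene does not check a knockout label, and the position of the deletion is not given in the sources used here. The direction of each knockout comparison below therefore rests on the labels.

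**Figure D1:**
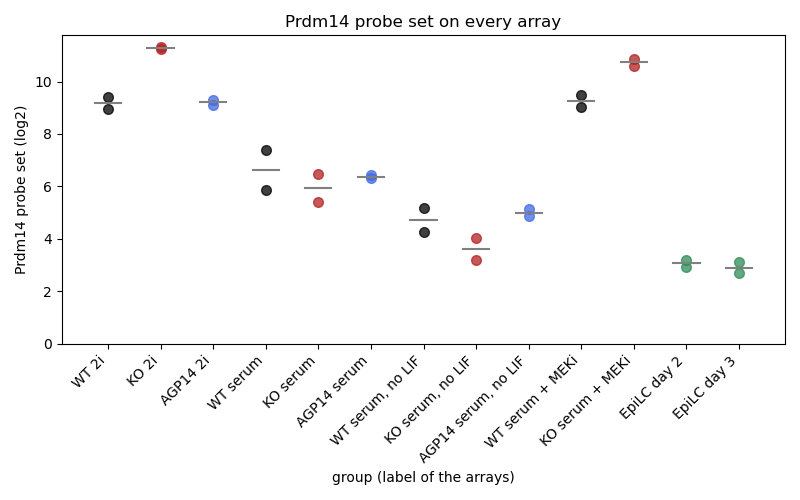
Log2 value of the Prdm14 probe set (y axis) on each of the 26 arrays (points) in the 13 groups (x axis), with the group mean as a grey line; black is wild type, red knockout, blue AGP14 and green EpiLC. In 2i the arrays labelled knockout lie at 11.33 and 11.24 and those of wild type at 8.95 and 9.40.

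In 2i, several transcripts fell steeply in the arrays labelled knockout. Slfn8, of the Schlafen family, fell by 6.37 (SE 0.33), from 8.56 ± 0.24 (SD, n = 2) to 2.19 ± 0.40. Slc38a4, an imprinted amino acid transporter gene, fell by 5.05 (SE 0.40), and Ccnb1ip1, whose product is needed for meiotic crossing over, fell by 3.83 (SE 0.20). Vwf, which encodes von Willebrand factor, fell by 4.76. Among the rises were Nt5e, the ecto-nucleotidase that makes adenosine, by 4.47 (SE 0.25), Trh, the precursor of thyrotropin-releasing hormone, by 3.02 and the imprinted gene Sgce by 2.66. In all, 661 genes rose and 1004 fell. Dnmt3l, the cofactor of the de novo DNA methyltransferases, rose by 3.07 (SE 0.17), to 11.07 ± 0.12, and Dnmt3b rose by 1.97. The maintenance enzyme gene Dnmt1 fell by 0.32. The median of the 6 methylation genes was 0.49 and the list's camera test did not pass (adjusted p = 0.0732, and adjusted p = 0.397 with an estimated correlation); 5 members were called when adjusted over the list alone. It passed without knockout replicate 2 (adjusted p = 0.0186) or wild-type replicate 1 (0.0019) and with the mean of probe sets (0.0323). Of 20 ERK response genes, 5 rose and none fell (6 when adjusted over the list alone), among them Spry4 (1.70), the receptor tyrosine kinase inhibitor Spry2 (1.24) and Myc (1.15). The list's camera adjusted p was 0.000108, and 0.143 with an estimated correlation. Germline genes went the other way, with 5 of 21 lower and none higher (6 over the list alone; adjusted p = 0.000193, and adjusted p = 0.397 with an estimated correlation). Hormad1 (-2.79) and Dazl (-2.40) were among them. In the LIF and STAT3 list, the STAT3 targets Bcl3 (-1.83) and Pim1 (-1.79) were among 4 that fell, and Socs3 rose by 0.66 as its single riser (5 over the list alone; adjusted p = 0.0129, and adjusted p = 0.397 with an estimated correlation). The LIF list lost its call without wild-type replicate 2 (0.0633). Naive pluripotency genes were mostly level, with 1 of 22 higher and 2 lower (4 over the list alone; adjusted p = 0.672). Klf5 fell by 0.95, a call that the mean of its probe sets did not keep in any medium, and Tcl1 fell by 1.42. A model of these 4 arrays alone called 25 genes. Leaving out wild-type replicate 1 gave 727 calls and leaving out knockout replicate 1 gave 1008, and the calls of Dnmt1, Spry4 and Socs3 depended on single arrays.

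In serum, the arrays labelled knockout had lower naive pluripotency genes. Of 22 in the list, 10 fell and none rose (14 when adjusted over the list alone), with a median of -0.69 (camera adjusted p = 1.89e-11, and adjusted p = 0.128 with an estimated correlation). Tcl1, a coactivator of the AKT kinase, fell by 1.83 (SE 0.30). Klf5 (-0.88) and the orphan nuclear receptor genes Nr5a2 (-1.58) and Nr0b1 (-1.36) were also among those that fell. Cholesterol synthesis genes rose, 5 of 18 with none lower (8 over the list alone; adjusted p = 7.41e-06, and adjusted p = 0.228 with an estimated correlation), among them Mvd (0.73) and Idi1 (0.66, SE 0.08). Over all genes 252 rose and 507 fell, and quantile normalization moved the share of rises from 33.2% to 50.1%. Slc38a4 fell by 5.37 (SE 0.40), from 9.77 ± 0.08 (SD, n = 2) to 4.40 ± 0.22. Ccnb1ip1 (-4.18), Slfn8 (-4.09) and the X-linked homeobox gene Rhox5 (-3.54) fell as well. Dnmt3l and Dnmt3b differed by -0.04 and 0.22, which did not pass. Oxidative phosphorylation genes shifted by a median of -0.12, with 4 of 25 lower (12 over the list alone; adjusted p = 5.15e-05, and adjusted p = 0.228 with an estimated correlation). The ERK response (1 of 20 higher), primordial germ cell (1 of 13 lower), germline (2 of 21 lower) and G2 and M (2 of 21 higher) lists passed too, with 2, 3, 7 and 4 members called over the list alone. Their adjusted p were 0.0118, 0.011, 0.0249 and 0.011, and adjusted p = 0.228, 0.320, 0.421 and 0.228 with an estimated correlation. Without wild-type replicate 1 the ERK and germline calls were lost (0.309 and 0.657), without its replicate 2 the germ cell and G2 and M calls (0.281 and 0.0740), without knockout replicate 2 the germline and G2 and M calls (both 0.0613), and with the mean of probe sets the G2 and M call (0.169). Feeder fibroblast markers lay at a mean of 6.66 in wild type and 6.80 in the arrays labelled knockout, with 1 of 27 higher (1 over the list alone; adjusted p = 0.0491, and adjusted p = 0.421 with an estimated correlation). The adjusted p was 0.0547 with the replicate number as a block, 0.0537 with the line as fixed columns and 0.0504 without the intensity trend. The call was also lost without replicate 1 of knockout (0.310) or of wild type (0.570). A model of these 4 arrays alone called 2 genes, and leaving out any of the 4 gave fewer calls, from 283 without knockout replicate 1 and 331 without its replicate 2 to 409 without wild-type replicate 2 and 443 without its replicate 1. Nr5a2 and Nr0b1 lost their calls without knockout replicate 1 or wild-type replicate 2.

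Without LIF, naive genes were again lower in the arrays labelled knockout. Of the list, 10 of 22 fell and none rose (16 when adjusted over the list alone), with a median of -0.70 (camera adjusted p = 4.54e-17, and adjusted p = 0.0307 with an estimated correlation). Nr5a2 (-2.19, SE 0.29), Nr0b1 (-2.08, SE 0.27), Klf2 (-1.31, SE 0.14) and Klf5 (-1.08) fell. Cholesterol synthesis genes rose, 6 of 18 with none lower (6 over the list alone; adjusted p = 2.78e-05, and adjusted p = 0.214 with an estimated correlation), including Mvd (0.83) and Idi1 (0.56). Over all genes 319 rose and 444 fell, with Slc38a4 (-4.85), Slfn8 (-4.73), Ccnb1ip1 (-3.93) and Rhox5 (-3.64) among the largest falls and Prex2, an exchange factor for RAC, up by 1.87. Germline genes had 4 of 21 lower, Hormad1 (-2.24) and Tex19.1 (-1.55) among them (6 over the list alone; adjusted p = 0.000347, and adjusted p = 0.272 with an estimated correlation). Primordial germ cell genes had 2 of 13 lower (4 over the list alone; adjusted p = 0.00015, and adjusted p = 0.214 with an estimated correlation). Oxidative phosphorylation genes had 3 of 25 lower (6 over the list alone; adjusted p = 7.64e-05, and adjusted p = 0.271 with an estimated correlation). ERK response genes had 2 of 20 higher (4 over the list alone; adjusted p = 0.026, and adjusted p = 0.271 with an estimated correlation), and gave 0.218 without wild-type replicate 1 and 0.0765 with dim genes left out. The polycomb list had 2 of 20 lower (2 over the list alone; adjusted p = 0.0485, and adjusted p = 0.170 with an estimated correlation). Of the settings that kept these 4 arrays, all but the replicate block ended this call (0.0552 to 0.425), and the mean of probe sets turned the median from -0.14 to 0.02. It was also lost without replicate 2 of knockout (0.201) or of wild type (0.203). Feeder markers were higher beside these groups, with a mean of 7.03 against 6.60 and a median difference of 0.42 (2 of 27 higher, 12 over the list alone; adjusted p = 3.35e-08, and adjusted p = 0.113 with an estimated correlation). Tagln (1.39) and Mmp2 (0.60) rose. A model of these 4 arrays alone called 20 genes, and leaving out knockout replicate 1 or 2 or wild-type replicate 1 gave 291, 347 and 329. The calls of Tagln, Mmp2 and Tex19.1 depended on single arrays.

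With MEK inhibitor, the arrays labelled knockout again had higher Nt5e (2.85, SE 0.25), Hs6st2, a heparan sulfate sulfotransferase gene (2.77, SE 0.17), Sgce (2.32) and Dnmt3l (1.15). The largest falls included Slfn8 (-5.24), Slc38a4 (-4.63), Ccnb1ip1 (-3.67), Rhox5 (-3.31) and the laminin gene Lama1 (-2.71). Over all genes 338 rose and 404 fell. In the LIF and STAT3 list 3 of 16 fell and none rose, namely Bcl3 (-1.41), Stat3 (-0.82) and Pim1 (-0.72) (5 when adjusted over the list alone; camera adjusted p = 0.00763, and adjusted p = 0.425 with an estimated correlation). That list gave 0.0510 without knockout replicate 1 and 0.139 without wild-type replicate 2. Naive genes had 1 of 22 higher and 2 lower, with a median of -0.14 (3 over the list alone; adjusted p = 0.0595). The adjusted p was 0.0497 with the replicate number as a block, 0.0484 with the line as fixed columns and 0.00174 in a model of these 4 arrays alone. A model of these 4 arrays alone called 21 genes. Leaving out knockout replicate 1 or 2 or wild-type replicate 1 gave 442, 460 and 334 calls.

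**Figure D2:**
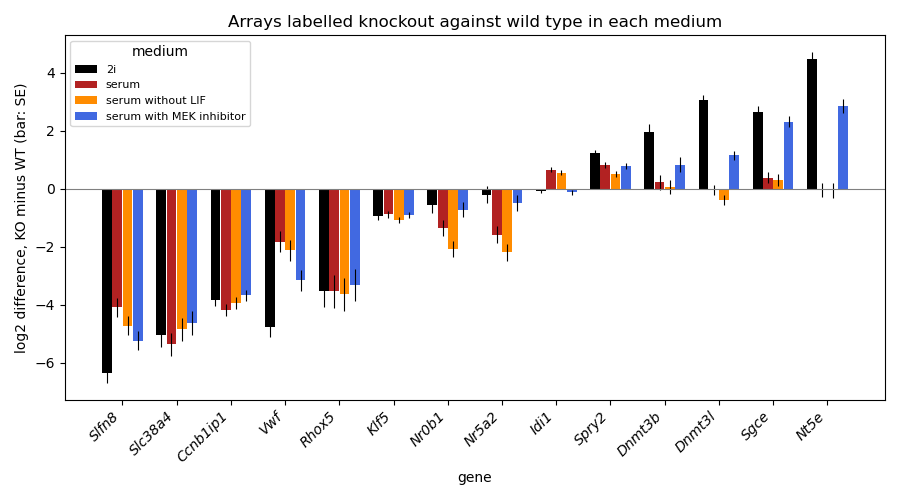
Log2 difference of the arrays labelled knockout minus wild type (y axis) for 14 genes (x axis) in 4 media (colours), 2 arrays per group; error bars are the standard error of the model. Slc38a4 lies at -5.05, -5.37, -4.85 and -4.63 in 2i, serum, serum without LIF and serum with MEK inhibitor.

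The genotype difference was partly shared between media and partly differed between them. In all 4 media 81 genes were lower and 24 were higher in the arrays labelled knockout, where independent lists would share 0.0152 of the lower kind. The media share no arrays, but arrays of the same number deviated together across media within wild type and within knockout, so part of each overlap can come from repeated lines. Between 2i and MEK inhibitor 283 lower genes were shared (22.3 for independent lists) and 202 higher (12.3). Between serum with and without LIF the numbers were 278 (12.4) and 138 (4.42), and between 2i and serum 173 (28.0) and 49 (9.16). Fixed line columns leave the spread between lines out of the error, so they cannot test genotype. With arrays of number 1 in the first medium and 2 in the other, and then the reverse, which was chosen after seeing the data, the shared lower genes were 83 (10.9) and 134 (12.3) for 2i and MEK inhibitor. They were 49 (1.61) and 73 (2.93) for serum with and without LIF, and 59 (10.6) and 34 (2.74) for 2i and serum. The genotype difference itself differed between serum and 2i for 541 genes, of which 247 were more positive in serum and 294 more negative (311 and 267 with quantile normalization). Nt5e (-4.51), Dnmt3l (-3.11) and Prdm14 (-2.81) were more negative in serum. As a list, naive genes were more negative in serum (4 of 22, 7 over the list alone, median -0.63, camera adjusted p = 1.99e-06). Cholesterol synthesis genes were more positive (7 of 18, 10 over the list alone, median 0.34, adjusted p = 5.29e-07). With an estimated correlation both had adjusted p = 0.241. Because each genotype difference is taken within a labelling batch, this interaction compares differences and not levels across batches. The count was 1746 with the line as fixed columns and 1217 with it as a random block, 325 without the intensity trend, 301 with the mean of probe sets and 15 in a model of these arrays alone. It was 224 without replicate 1 of knockout in serum, 269 without replicate 1 of wild type in 2i, and 280, 304 and 312 without knockout replicate 2 in serum, wild-type replicate 2 in serum and knockout replicate 1 in 2i. With MEK inhibitor, across the same batches, the genotype difference differed from that in serum for 42 genes. Of these, 25 went upwards and 17 downwards (21 and 25 with quantile normalization). By list, naive genes were shifted by a median of 0.41 with none called (2 over the list alone, adjusted p = 1.39e-05). Cholesterol synthesis genes shifted by -0.30 with 2 lower (7 over the list alone, adjusted p = 1.62e-08). Feeder markers shifted with them, by -0.37 (adjusted p = 3.41e-05). With an estimated correlation each had adjusted p = 0.262. Without wild-type replicate 1 in serum the naive and feeder medians were 0.66 and -0.21, and without knockout replicate 1 with the inhibitor the feeder median was -0.23. The count of 42 was 612 with the line as fixed columns, 243 with it as a random block and 64 with the replicate number as a block. It was 72 with dim genes left out, 21 with the mean of probe sets, 20 without the intensity trend, 20 without knockout replicate 1 in serum and 0 in a limma model of these arrays alone (1282 at an unadjusted p under 0.05). For the loss of LIF limma called 0 genes, with 654 at an unadjusted p under 0.05. As lists, naive genes had a median of -0.08 with none called (2 over the list alone, adjusted p = 0.0342). Feeder markers had 0.26 with none called (0 over the list alone, adjusted p = 0.000293). With an estimated correlation they had adjusted p = 0.721 and 0.667. The naive call was lost without knockout replicate 1 (0.302) or wild-type replicate 2 (0.780) in the medium without LIF and without knockout replicate 2 (0.199) or wild-type replicate 1 (0.944) in serum. It was also lost with quantile normalization (0.0564), the mean of probe sets (0.262), no intensity trend (0.0801) and the arrays of the compared groups (0.107). The feeder call was lost without replicate 1 of knockout (0.176) or of wild type (0.187) in the medium without LIF, without replicate 2 of knockout (0.0858) or of wild type (0.0927) in serum, and with the mean of probe sets (0.0725). There were 3 calls with the line as fixed columns, 2 with it as a random block, 1 with the replicate block, 1 without wild-type replicate 1 in the medium without LIF, and 2 without wild-type replicate 1 in serum.

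The AGP14 arrays came from knockout cells that carry the Prdm14 transgene. In serum, against the arrays labelled knockout, 15 of 22 naive genes rose and none fell (15 when adjusted over the list alone), with a median of 0.76 (camera adjusted p = 4.5e-17, and adjusted p = 0.0307 with an estimated correlation). Tcl1 rose by 2.93, the transcription factor genes Tfcp2l1 by 2.66 and Nanog by 1.62 (SE 0.18), and Klf5 by 0.94. Primed genes fell, 11 of 24 with 1 higher (14 over the list alone; adjusted p = 0.000543, and adjusted p = 0.163 with an estimated correlation), among them Pim2 (-2.47) and Wnt8a (-1.72). LIF and STAT3 genes rose, 5 of 16 (8 over the list alone; adjusted p = 2.47e-05, and 0.0402 with an estimated correlation). Primordial germ cell genes rose, 5 of 13 (5 over the list alone; adjusted p = 7.5e-05, and adjusted p = 0.183 with an estimated correlation). Over all genes 952 rose and 960 fell. Slc38a4 rose by 4.86, Obox6 by 4.37 and Serpinb6c by 4.03. The imprinted gene Nnat fell by 5.13, to 2.31 ± 0.94 (SD, n = 2) from 7.44 ± 0.86. Oxidative phosphorylation genes had 4 of 25 higher (adjusted p = 9.52e-05, and adjusted p = 0.232 with an estimated correlation) and G2 and M genes 7 of 21 lower (8 over the list alone; adjusted p = 0.00237, and adjusted p = 0.192 with an estimated correlation). Feeder markers moved with these groups: their mean was 7.11 in AGP14 and 6.80 in knockout, with 4 of 27 higher and 2 lower (11 over the list alone; adjusted p = 0.000636, and adjusted p = 0.232 with an estimated correlation). Leaving out any of the 4 arrays lowered the count, to 1110 and 882 without AGP14 replicate 1 and 2, and to 959 and 1169 without knockout replicate 1 and 2.

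Without LIF the same comparison gave larger naive gene values. Of 22 naive genes 19 rose and none fell (20 when adjusted over the list alone), with a median of 1.44 (camera adjusted p = 8.22e-27, and 0.00453 with an estimated correlation). Nr5a2 rose by 4.44, Tcl1 by 3.99 and Klf4 by 2.91. Primordial germ cell genes rose, 8 of 13 (8 over the list alone; adjusted p = 1.15e-06, and adjusted p = 0.071 with an estimated correlation), and so did LIF and STAT3 genes, 6 of 16 (7 over the list alone; adjusted p = 0.000484, and adjusted p = 0.071 with an estimated correlation). Of 24 primed genes 8 fell and 2 rose (11 over the list alone; adjusted p = 0.00399, and adjusted p = 0.159 with an estimated correlation). Pim2 (-2.73) and Wnt8a (-2.52) fell, while Lef1 rose by 0.83. Over all genes 1471 rose and 950 fell, and quantile normalization moved the share of rises from 60.8% to 49.0%. Serpinb6c rose by 6.96, Slc38a4 by 4.78 and the glutamate decarboxylase gene Gad1 by 4.65. Nnat (-5.99) and the desmosomal cadherin gene Dsc2 (-4.10) fell. DNA demethylation (3 of 11 higher; adjusted p = 0.00399, and adjusted p = 0.137 with an estimated correlation), polycomb (6 of 20 higher and 1 lower; adjusted p = 0.0117, and adjusted p = 0.071 with an estimated correlation) and oxidative phosphorylation (4 of 25 higher and 1 lower; adjusted p = 0.0102, and adjusted p = 0.509 with an estimated correlation) also passed. The mean of the feeder markers was 7.33 in AGP14 and 7.03 in knockout, with 6 of 27 higher and 2 lower (14 over the list alone; adjusted p = 0.0102, and adjusted p = 0.399 with an estimated correlation), a call lost without knockout replicate 2 (0.0969) or with dim genes left out (0.0536). Leaving out AGP14 replicate 1 or 2 gave 1468 and 1290 calls, and leaving out knockout replicate 1 or 2 gave 1498 and 1543.

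Against wild type, naive genes were higher in AGP14 arrays in both serum media. In serum 6 of 22 were higher and none lower (9 when adjusted over the list alone; camera adjusted p = 0.000246, and adjusted p = 0.335 with an estimated correlation), among them Tfcp2l1 (1.67) and Nanog (0.89). Without LIF 14 were higher and none lower (16 over the list alone; adjusted p = 7.35e-13, and 0.0442 with an estimated correlation), with Tfcp2l1 at 2.43, Klf4 at 2.31 and Nanog at 1.54. Primed genes were lower in serum (5 of 24, 10 over the list alone; adjusted p = 0.0275, and adjusted p = 0.335 with an estimated correlation) and without LIF (4 lower and 1 higher, 9 over the list alone; adjusted p = 0.025, and adjusted p = 0.314 with an estimated correlation), and both calls were lost with dim genes left out (0.143 and 0.127). LIF and STAT3 genes were higher in serum (4 of 16, with 1 lower; adjusted p = 0.00373, and adjusted p = 0.246 with an estimated correlation) and without LIF (7, with 1 lower; adjusted p = 0.000134, and adjusted p = 0.051 with an estimated correlation). A direction shared with knockout can come from the shared wild-type arrays. In serum it was seen for ERK response genes (1 of 20 higher and 1 lower, 4 over the list alone, median 0.30, adjusted p = 0.0233, and 0.335 with an estimated correlation). Cholesterol synthesis genes shared it too (2 of 18 higher, 5 over the list alone, median 0.14, adjusted p = 0.0195, and 0.442 with an estimated correlation). Both calls were lost without AGP14 replicate 1 (0.0758 and 0.0933), and the first without wild-type replicate 1 (0.347). Without LIF these lists had adjusted p of 0.0565 and 0.117. Slfn8 was still -4.61 in serum and -4.07 without LIF, Ccnb1ip1 -3.57 in serum and Nnat -4.73 and -5.78. Feeder markers were higher beside the naive genes, with means of 7.11 against 6.66 in serum (9 of 27 higher and 1 lower, 18 over the list alone; adjusted p = 1.19e-08, and adjusted p = 0.172 with an estimated correlation) and 7.33 against 6.60 without LIF (18 higher and 1 lower, 22 over the list alone; adjusted p = 7.35e-13, and 0.0442 with an estimated correlation). Over all genes 428 rose and 839 fell in serum, and 1153 rose and 788 fell without LIF. In serum quantile normalization moved the share of rises from 33.8% to 47.8%. In serum the count was 153 without wild-type replicate 1, with which the calls of Tfcp2l1, Nanog and of the naive and primed lists (both 0.0521) were lost, and 350 and 207 without AGP14 replicate 1 and 2. Without LIF it was 462 without wild-type replicate 1, and 751 and 673 without AGP14 replicate 1 and 2.

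In 2i the AGP14 arrays and the other arrays were in different labelling batches, so genotype and batch cannot be told apart in that medium. There, 1495 genes were higher and 2906 lower than in the arrays labelled knockout, and 1305 higher and 3309 lower than in wild type. Quantile normalization moved the share of higher genes from 34.0% to 59.1% and from 28.3% to 57.5%, and the median of all genes from -0.03 to 0.09 and from -0.08 to 0.06. Against knockout, Obox6 (4.76) and Rhox5 (4.62) were higher, and Igf2 (-3.45), Malat1 (-3.65) and, at a dim level, Nnat (-3.65) lower. Against wild type, Slfn8 (-6.79) and Igf2 (-3.87) were lower, and Nt5e (3.13) higher. Against knockout 9 of 27 feeder markers were lower, and 9 of 21 G2 and M genes with 1 higher (adjusted p = 0.0434 and 0.00505, and adjusted p = 0.658 and 0.647 with an estimated correlation). Against wild type 12 feeder markers, 12 G2 and M genes with 2 higher, 6 of 22 naive genes and 5 of 14 housekeeping genes were lower (adjusted p = 0.014, 0.00118, 0.0229 and 0.0368, and adjusted p = 0.464, 0.411, 0.491 and 0.461 with an estimated correlation). Oxidative phosphorylation (11 of 25), cholesterol synthesis (8 of 18) and DNA demethylation genes (6 of 11) were also lower than in wild type (adjusted p = 0.0104, 0.0368 and 0.0460, and adjusted p = 0.491, 0.507 and 0.461 with an estimated correlation). Without AGP14 replicate 1 or 2 the counts were 2916 and 2858 against knockout and 2807 and 2930 against wild type, which gave 2877 without wild-type replicate 1.

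Genes called in knockout against wild type in 1 medium were followed in the AGP14 arrays of another medium. No array was shared, but knockout arrays of the same number deviated together across media (correlation 0.468 to 0.739) and entered these differences with opposite signs, which the shares over all genes leave out. Of the 507 genes lower in knockout in serum, 92.7% had the opposite sign in AGP14 against knockout without LIF and 57.6% were called upwards, against 50.9% and 8.09% of all genes. Of the 444 lower without LIF, 84.9% turned in serum and 43.9% were called, against 48.3% and 5.23% of all genes. Of the genes higher in knockout, 85.7% of 252 (serum) and 79.6% of 319 (without LIF) turned, and 42.5% and 31.0% were called. Of the genes called in 2i, 65.2% of the 1004 lower and 66.6% of the 661 higher turned in AGP14 in serum, and 68.8% and 59.5% without LIF. Those called with MEK inhibitor turned in 85.9% (lower) and 85.2% (higher) in serum and 88.1% and 77.2% without LIF. The shares were then taken with knockout replicate 1 in the calls and 2 in the AGP14 comparison, and the reverse, a check chosen after seeing the data. Of the genes lower in serum 84.8% of 257 and 90.8% of 238 turned, against 49.4% and 51.2% of all genes, and of those lower without LIF 83.5% of 249 and 81.3% of 208, against 47.0% and 48.1%. Of the genes higher in serum 74.2% of 89 and 85.1% of 47 turned, and of those higher without LIF 68.7% of 115 and 66.7% of 84. Within a medium the knockout arrays enter both differences. The covariance of the differences across genes was -0.133 in 2i, -0.135 in serum and -0.135 without LIF, against simulated values of -0.0737, -0.0737 and -0.0740 with no effect. Of the 81 genes lower in all 4 media, 52 were moved back in both serum media, among them Slc38a4, Rhox5, Serpinb6c, Gm21283, Hormad1 and Tcl1. Another 11 were not moved back in serum and still differed from wild type in both media, Slfn8, Trim25 and Mks1 among them; of these, Ccnb1ip1 (0.86, adjusted p = 0.00611), Gpat2 (1.01), Ash2l (0.37) and Snhg6 (0.30) rose without LIF. Of the 24 higher genes 12 were moved back in both media, and 6, including Prex2, Spry2 and Flna, in neither, and still differed from wild type in both. Of these, Haus4 rose further, by 0.25 in serum and 0.26 without LIF.

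Serum against 2i changes the base medium and adds serum as well as leaving out the MEK and GSK3 inhibitors. In wild type the homeobox gene Otx2 rose by 6.05, the carbonic anhydrase gene Car4 by 5.41 and the Notch ligand gene Dll1 by 4.41. The de novo methylation genes Dnmt3a (3.77), Dnmt3l (3.69) and Dnmt3b (3.39) rose, and 4 of the 6 methylation genes were higher and 2 lower (6 when adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.189 with an estimated correlation, 0.0706 with dim genes left out and 0.0602 in these arrays alone). Of 20 ERK response genes 12 rose and 1 fell (13 over the list alone; adjusted p = 1.45e-05, and 0.0375 with an estimated correlation), with Myc at 3.55 and Spry4 at 3.45. Primed genes rose, 16 of 24 with 2 lower (18 over the list alone; adjusted p = 1.45e-05, and 0.0375 with an estimated correlation). Naive genes fell, 14 of 22 with 2 higher (17 over the list alone; adjusted p = 0.000117, and adjusted p = 0.295 with an estimated correlation), Tfcp2l1 by -3.07 and Nanog by -1.62. All 18 cholesterol synthesis genes fell (adjusted p = 5.16e-14, and 0.0279 with an estimated correlation), Dhcr7 by -1.68. In knockout Fgf5 (6.06) and Otx2 (5.56) rose, 17 naive genes fell with 2 higher (19 over the list alone; adjusted p = 2.66e-08, and adjusted p = 0.122 with an estimated correlation), Nanog by -2.37, and 12 cholesterol synthesis genes fell (14 over the list alone; adjusted p = 5.17e-07, and adjusted p = 0.122 with an estimated correlation). These comparisons crossed the labelling batches. In AGP14, within 1 batch, Otx2 (4.71) and Egr1 (4.48) rose, 12 ERK response genes rose and none fell (15 over the list alone; adjusted p = 2.33e-09, and 0.00706 with an estimated correlation), and 17 cholesterol synthesis genes fell (18 over the list alone; adjusted p = 1.94e-15, and 0.00964 with an estimated correlation). Feeder markers fell in all 3 genotypes: 20 of 27 in wild type, median -2.12, 20 in knockout, median -1.98, and 18 in AGP14, median -1.03 (adjusted p = 2.99e-15, 1.44e-13 and 1.47e-15; 0.023, 0.0363 and 0.00706 with an estimated correlation). Counts were 6286 in wild type (2760 up), 6506 in knockout (2872 up) and 3309 in AGP14 (1814 up). The share of rises moved from 43.9% to 55.2% in wild type and from 44.1% to 57.5% in knockout with quantile normalization. Of the wild-type calls 2135 were called the same way in AGP14 and 159 the opposite way. In AGP14 the count was 1735 without replicate 1 in serum, and 2099 and 1969 without replicate 1 and 2 in 2i.

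Removal of LIF from serum lowered STAT3 targets, and naive genes in wild type and knockout. In wild type Socs3, the feedback inhibitor of the LIF receptor, fell by 2.02 (SE 0.18), and Bcl3 (-1.84) and Klf5 (-1.14) fell. In knockout Socs3 (-1.85), Nr0b1 (-2.37) and Nr5a2 (-2.29) fell, and in AGP14 Socs3 fell by 2.48. The Prdm14 probe set changed by -1.91 in wild type and -2.31 in knockout. In AGP14 its value was -1.39 and did not pass (adjusted p = 0.169), but was called with the repeated lines as a block. LIF and STAT3 genes fell, 8 of 16 in wild type (9 when adjusted over the list alone), 6 in knockout (9) and 2 in AGP14 (5), with camera adjusted p of 1.16e-09, 3.81e-08 and 1.57e-07, and 0.00478, 0.00757 and 0.0232 with an estimated correlation. Naive genes fell, 15 of 22 in wild type (16 over the list alone) and 13 in knockout (17), with adjusted p of 1.13e-22 and 6.1e-33, and 0.00478 and 0.00172 with an estimated correlation. In AGP14 1 naive gene fell (3 over the list alone; adjusted p = 3.64e-08, and adjusted p = 0.130 with an estimated correlation). Klf4 (-1.97), Tfcp2l1 (-1.84) and Nr5a2 (-1.69) fell in wild type. Feeder markers in knockout had a median of 0.24 with none called (adjusted p = 0.000419, and adjusted p = 0.154 with an estimated correlation). Over all genes 60 rose and 213 fell in wild type, 49 and 151 in knockout, and 21 and 34 in AGP14. The share of rises moved from 22.0% to 44.0% in wild type and from 24.5% to 36.8% in knockout with quantile normalization. With the repeated lines as a block (fixed columns), 1215, 837 and 641 genes were called, and with the replicate number as a block AGP14 had 103. The AGP14 split turned, to 405 up and 236 down with fixed columns, 202 and 124 with a random block and 313 and 205 in the 4 arrays alone; with the replicate block it was 51 and 52. Limma models of 4 arrays alone called 0 genes in wild type (1625 at an unadjusted p under 0.05), 9 in knockout and 518 in AGP14. In wild type the count was 35 without replicate 2 in serum, with which Klf4, Tfcp2l1 and Nr5a2 lost their calls, and 48 without replicate 1 without LIF. In knockout it was 101 and 91 without replicate 1 and 2 in serum and 84 and 111 without those lacking LIF, and in AGP14 it was 25, 16, 5 and 18 in the same order.

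Serum with the MEK inhibitor had higher naive genes and lower ERK response genes than serum alone in both genotypes. In wild type 15 of 22 naive genes rose and none fell (16 when adjusted over the list alone; camera adjusted p = 1.42e-06, and adjusted p = 0.228 with an estimated correlation), Tfcp2l1 by 2.44 and Nanog by 1.62. In knockout 18 rose (18 over the list alone; adjusted p = 2.36e-12, and adjusted p = 0.0995 with an estimated correlation), Nanog by 2.26. ERK response genes fell, 8 of 20 with 2 higher in wild type (11 over the list alone; adjusted p = 0.000857, and adjusted p = 0.210 with an estimated correlation) and 10 with 1 higher in knockout (13 over the list alone; adjusted p = 0.000246, and adjusted p = 0.116 with an estimated correlation). In wild type and knockout, Spry4 lay at -2.24 and -2.23 and Etv4 at -2.02 and -2.78. In wild type Dnmt3a (-2.09), Dnmt3b (-1.33) and Dnmt3l (-1.02) fell. These comparisons crossed the labelling batches, no batch held both media, and the inhibitor and the batch cannot be told apart. Feeder markers rose beside the naive genes, 20 of 27 with 2 lower in wild type, median 1.28, and 18 with 1 lower in knockout, median 0.77 (22 and 20 over the list alone; adjusted p = 1.96e-11 and 2.14e-06, and adjusted p = 0.0682 and 0.116 with an estimated correlation). Over all genes 2597 rose and 2033 fell in wild type, and 2721 and 1740 in knockout. The share of rises moved from 56.1% to 40.6% and from 61.0% to 40.2% with quantile normalization. The count was 2980 without wild-type replicate 1 in serum, 2973 without wild-type replicate 2 with the inhibitor, and in knockout 2940 without replicate 2 with the inhibitor.

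Within the labelling batch of high lys signal, serum with MEK inhibitor was set against 2i, which holds the same inhibitor. All 18 cholesterol synthesis genes fell in wild type and 16 in knockout (adjusted p = 7.41e-26 and 5.49e-24, and 0.00405 and 0.00384 with an estimated correlation). Otx2 rose by 4.72 in wild type, Car4 rose by 4.00 and 4.42, and the Wnt-responsive gene Cdx1 fell, at -4.03 and -3.31. Prdm14 differed by 0.09 in wild type and -0.55 in knockout, which did not pass. Feeder markers were lower, with medians of -1.29 and -1.14 (18 and 19 of 27 fell; adjusted p = 1.53e-16 and 4.3e-20). Over all genes 992 rose and 1285 fell in wild type and 1202 and 1199 in knockout. With the repeated lines as a block the counts were 3875 and 3962, models of the 4 arrays alone called 273 and 472, and leaving out replicate 1 with the inhibitor gave 1446 in wild type and 1452 in knockout.

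**Figure D3:**
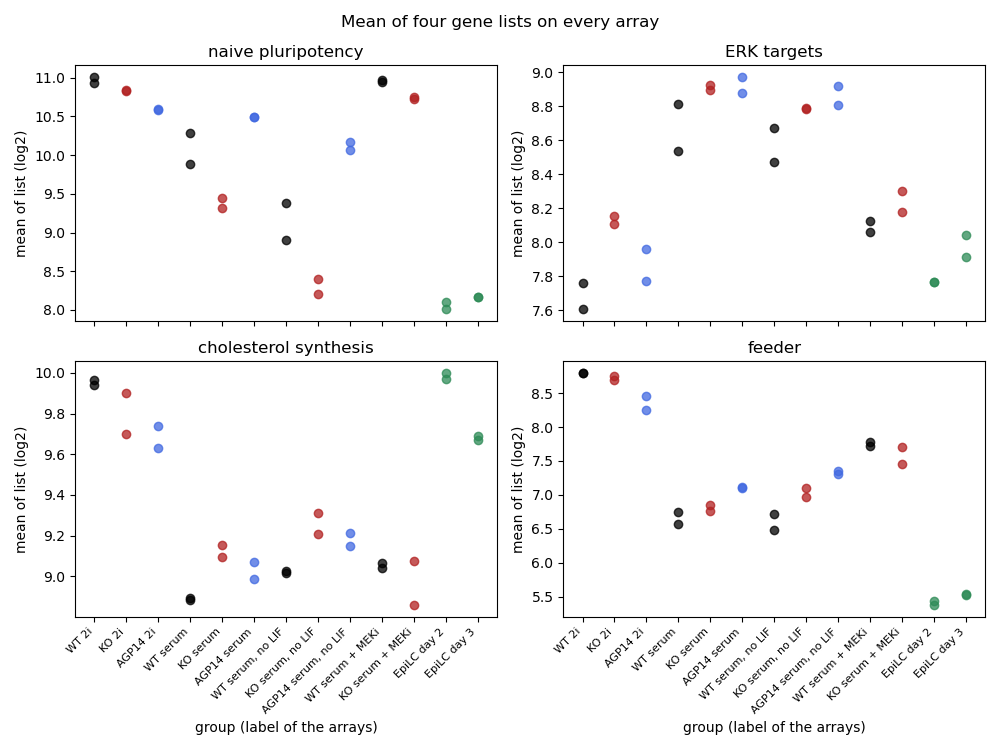
Mean log2 value of the naive pluripotency, ERK response, cholesterol synthesis and feeder fibroblast lists (y axes) on each of the 26 arrays (points) in the 13 groups (x axis); black is wild type, red knockout, blue AGP14 and green EpiLC. The naive mean is 9.15 in wild type, 8.30 in knockout and 10.11 in AGP14 without LIF, and the feeder mean is 8.80 in wild type in 2i and 5.40 in EpiLC of day 2.

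EpiLC, the formative state that precedes germ cell induction in culture, differed from wild-type cells in 2i in both line and culture. On day 2 Car4 rose by 8.38, Fgf5, a classical epiblast gene, by 6.25, and Otx2 by 5.74. Naive genes fell, 18 of 22 with 1 higher (20 when adjusted over the list alone; camera adjusted p = 5.18e-14, and 0.0231 with an estimated correlation), Nr5a2 by -5.86, Tcl1 by -5.46 and Klf2 by -5.41. LIF and STAT3 genes fell, 13 of 16 with 1 higher (14 over the list alone; adjusted p = 2.92e-08, and 0.00782 with an estimated correlation), Socs3 by -3.88. Primed genes rose, 15 of 24 with 4 lower (19 over the list alone; adjusted p = 5.39e-06, and 0.0304 with an estimated correlation). Feeder markers fell beside these, 22 of 27 with 2 higher, median -3.31 (24 over the list alone; adjusted p = 7.64e-18, and 0.00782 with an estimated correlation), Col3a1 by -8.96. From day 2 to day 3 primed genes fell, 11 of 24 with none higher (14 over the list alone; adjusted p = 2.49e-05, and adjusted p = 0.126 with an estimated correlation), among them Zic2 (-1.51) and Lefty1 (-1.18), and cholesterol synthesis genes fell, 8 of 18 (10 over the list alone; adjusted p = 0.000625, and adjusted p = 0.433 with an estimated correlation). The counts were 6966 genes on day 2 (3136 up), 7367 on day 3 (3141 up) and 3198 between the days (1436 up). The last was 2042 without replicate 2 of day 3, and 2044 and 2055 without replicate 1 and 2 of day 2.

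The EpiLC comparisons gave a set of 195 genes higher and 411 genes lower on both days by at least 4-fold, which was then followed in the genotype comparisons that share no array with them. In serum the higher genes were shifted upwards in the arrays labelled knockout, by a median of 0.40, and the lower genes downwards, by -0.31 (camera adjusted p = 2.37e-11 and 1.1e-09, and adjusted p = 0.0899 with an estimated correlation for both). Without LIF the medians were 0.27 and -0.12 (adjusted p = 7.42e-06 and 0.00684, and adjusted p = 0.356 with an estimated correlation for both), and with MEK inhibitor 0.27 and -0.30 (adjusted p = 1.66e-06 and 5.69e-14, and adjusted p = 0.218 and 0.0367 with an estimated correlation). In AGP14 against knockout the direction was opposite, with -1.03 and 0.70 in serum and -0.87 and 0.68 without LIF, and adjusted p of 0.00704, 0.00212, 0.0159 and 0.00257 with an estimated correlation. In 2i the wild-type arrays are shared, and unchanged groups gave 0.0818 to 0.210 and -0.0985 to -0.0398 in 100 simulations. The medians, 0.22 and -0.20, are left undecided. Wild-type arrays of the same number also deviated together between 2i and the serum media. With wild-type replicate 1 in 2i and 2 in serum, a check chosen after seeing the data, the medians were 0.46 and -0.48 in serum, 0.35 and -0.17 without LIF and 0.49 and -0.37 with MEK inhibitor. All 6 passed, with adjusted p = 0.0237, 0.00677, 0.0761, 0.0761, 0.0149 and 0.0149 with an estimated correlation. With the numbers exchanged they were 0.11 and -0.15 in serum (both adjusted p = 0.00959, and adjusted p = 0.482 with an estimated correlation). They did not pass without LIF, at 0.07 and -0.03 (adjusted p = 0.357 and 0.911), nor for the higher genes with MEK inhibitor, at -0.09 (0.980), whereas the lower genes there had -0.20 (adjusted p = 3.85e-05, and adjusted p = 0.396 with an estimated correlation). The lower set holds 18 feeder markers and the higher set 1. Without wild-type replicate 2 the median of the higher genes with MEK inhibitor was -0.02 and that of the lower genes without LIF was -0.07, and both calls were lost.

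The remaining lists did not pass the camera test in knockout against wild type in 2i. Core pluripotency genes had 2 higher and 1 lower, FGF ligands and receptors 2 and 1, Wnt response genes 2 and 0, extraembryonic endoderm genes 0 and 2, mesoderm genes 2 and 1, neuroectoderm genes 0 and 2, trophoblast genes 2 and 0 and primordial germ cell genes 2 and 1. Polycomb genes had 2 and 2, HOX genes 2 and 0, DNA demethylation genes 1 and 2, glycolysis genes 2 and 4, oxidative phosphorylation genes 0 and 3 and cholesterol synthesis genes 0 and 4. G2 and M genes had 3 and 3, p53 response genes 1 and 1, genes of the 2-cell-like state 0 and 1 and housekeeping genes 0 and 1. Primed genes had 3 higher and 1 lower (9 when adjusted over the list alone; adjusted p = 0.0732), and feeder markers none higher and 1 lower, with a median of -0.07 (adjusted p = 0.672). In serum, LIF and STAT3 genes had 3 lower (adjusted p = 0.119) and DNA methylation genes none of either kind (adjusted p = 0.770). With MEK inhibitor germline genes had 2 lower and feeder markers 2 lower (both adjusted p = 0.0595).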

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

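The tests on the Prdm14 probe set and on the feeder markers were chosen after the results they bear on had been seen; those on the genes that AGP14 did not move back in serum were written before.

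The genotype difference differed between serum and 2i for 541 genes in the interaction test. Among the named ones it was more negative in serum for Nt5e (-4.51), Cd200r3 (-3.66, although its further probe set gave 1.40), Trh (-3.30), Dnmt3l (-3.11), Enox1 (-3.04), Prdm14 (-2.81), Dnmt3b (-1.75), Plet1 (-1.49), Zfp42 (-0.65), Gdf3 (-0.63) and Mybl2 (-0.47). It was more positive for Clec3b (4.14), Prss3 (4.09), Tmem163 (4.00), E130218I03Rik (3.95), 4931431C16Rik (3.83), Pim1 (2.10), Mvd (1.31), Dhcr7 (0.89), Idi1 (0.74) and Hmgcs1 (0.42). By list, the medians were -0.63 for naive pluripotency, -0.39 for DNA methylation and 0.34 for cholesterol synthesis, and all 3 calls were lost with an estimated correlation (adjusted p = 0.241 each). The methylation list had 2 of 6 members called (2 when adjusted over the list alone) and an adjusted p of 0.0319; its call was lost without replicate 1 of knockout (0.0915) or replicate 2 of wild type (0.113) in 2i, and without replicate 2 of knockout (0.123) or of wild type (0.0795) in serum. It was also lost without the intensity trend (0.0625) and with dim genes left out (0.104). Without wild-type replicate 2 in serum the naive median was -0.41.

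MEK inhibitor changed the genotype difference in serum for 42 genes, using the same serum arrays with opposite sign. The named values were Vinac1 (3.68), Nt5e (2.89), Hs6st2 (2.52), Sgce (1.93), Naprt (1.81) and Plet1 (1.41) upwards, and Iqcf5 (-3.24), Clec3b (-3.19), 2300002M23Rik (-2.82), Pga5 (-2.16), Zmynd8 (-1.37), Pim1 (-1.03), Idi1 (-0.79) and Hmgcs1 (-0.62) downwards. List medians were 0.41 for naive pluripotency, -0.30 for cholesterol synthesis and -0.37 for feeder markers, with adjusted p = 0.262 each with an estimated correlation. Without wild-type replicate 1 in serum the naive and feeder medians were 0.66 and -0.21, and without knockout replicate 1 with the inhibitor the feeder median was -0.23. Trophoblast (0.45), primordial germ cell (0.39), oxidative phosphorylation (0.08) and p53 response (-0.20) lists passed too, but not with an estimated correlation (adjusted p = 0.288, 0.361, 0.388 and 0.328), nor without replicate 2 of knockout (0.214 for the first 3) or, for p53, replicate 1 (0.459) with the inhibitor. With dim genes left out the first 2 lost their calls (0.0599 and 0.0603), with the mean of probe sets the first (0.160), and without the trend or in these arrays alone the p53 list (0.0670 and 0.0636). For the loss of LIF, the medians were -0.08 in naive genes and 0.26 in feeder markers. Both list calls were lost with an estimated correlation (adjusted p = 0.721 and 0.667). The spike-in control lys, by which the labelling batches were found, differed by 6.33 between them.

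The Prdm14 probe set was higher in the arrays labelled knockout in 2i and with MEK inhibitor. Swapped labels in these media would turn the genes that were lower in knockout in both serum media upwards, but the median of these 278 genes was -0.36 in 2i and -0.33 with MEK inhibitor, which argues against a swap. The difference between labelling batches is argued against by the value within 1 batch, 2.11 (SE 0.41). A transcript that is left after the deletion and released from its own repression in every medium would be higher in serum too, yet the value was -1.10 without LIF and -0.70 in serum. A release only in media with MEK inhibitor was not tested and stays open.

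Slfn8, Ccnb1ip1 and 15 further genes were apart in the arrays labelled knockout in all 4 media, were not moved back by AGP14 in serum and still differed from wild type in serum with and without LIF, although Ccnb1ip1 (0.86), Gpat2 (1.01), Ash2l (0.37) and Snhg6 (0.30) rose without LIF. A passenger region would place them near Prdm14. Only its chromosome was compared (2 of 17 there, Fisher's exact test, one-sided, p = 0.264, exact upper limit 36.4%, against 5.88% of all genes), not the distance. EpiLC, another cell state with the lowest Prdm14 levels, cannot test a difference that the lines had before the knockout. There, 7 of 17 lay nearer to knockout than to wild type. Of the genes moved back in both media 42 of 64 did (Fisher's exact test p = 0.0942). Slfn8 lay at 2.50 and 2.08 in EpiLC (2.19 in knockout in 2i) and Ccnb1ip1 at 7.86 and 7.37 (8.02 in wild type). Both explanations stay open. A biological effect of Prdm14 that the transgene does not restore was not tested.

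Feeder markers were lower in serum than in 2i. A lower share of feeder RNA may account for this: within 1 batch, in AGP14, 22 of 27 markers were lower in serum, and all 5 of the markers most abundant in 2i were, Col3a1 (-3.37), Col1a2 (-2.42), Bgn (-0.96), Fstl1 (-0.88) and Vim (-0.24, adjusted p = 0.133). The difference between labelling batches as the whole cause is argued against by the medians within a batch, -1.03 in AGP14 and -1.29 for MEK inhibitor against 2i in wild type. A change in the feeder cells themselves, or in stem cells that express these genes, was not tested.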

How the results depend on the processing

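The models with the line as fixed columns or as a random block, the signature without feeder markers, and different lines on the sides of a signature or share, were chosen after seeing the data; all other settings were planned. Of 26 counts of called genes, 3 stayed within 1.5 times in every setting and 6 in every setting that kept all arrays. Of 443 gene values, 249 kept direction and call in every setting and 261 in those that kept all arrays. Another 2 reversed, both of Klf5 with the mean of its probe sets: -0.067 for serum against 2i and 0.085 for LIF withdrawal, in AGP14. Of 90 list results 27 kept their call throughout, and an estimated correlation ended 60. The naive list in the LIF interaction had medians from -0.3725 to 0.0225 with each array left out, and its test turned without wild-type replicate 2 in the medium without LIF (0.0225) and wild-type replicate 1 in serum (-0.0075). Of 6 signature results 1 kept its call throughout. Of 12 shares of turned genes 0 stayed within their interval in every setting, and 6 did in those that kept all arrays. Quantile normalization kept all 26 counts and 443 gene values and ended 2 list calls, that of polycomb genes without LIF and that of naive genes in the LIF interaction. With dim genes left out, 57 gene values were not tested and none of the others lost its call or turned, but 10 list calls ended. Models of the compared groups ended 4 list calls and gave 2, the mean of probe sets ended 5 and gave 1, no intensity trend ended 5, and the line as fixed columns ended 2 and gave 2. Of 84 list results that were called, 21 kept the call but moved by over 1.5 times in their median without some array. Fewer arrays or genes are part of some settings by construction; beyond that the cause was not tested. Signal over background is not given per probe, so the floor of 0 sets no detection limit.

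In models of the compared groups alone, knockout against wild type had 25, 2, 20 and 21 calls in 2i, serum, serum without LIF and serum with MEK inhibitor. AGP14 against wild type had 2963, 196 and 930 in 2i, serum and serum without LIF, serum against 2i in wild type 3664, LIF withdrawal 0 in wild type (limma; 1625 at an unadjusted p under 0.05), 9 in knockout and 518 in AGP14, and MEK inhibitor 1822 and 2602. The interaction of serum with 2i had 15, that of MEK inhibitor 0 (1282 unadjusted), and MEK inhibitor against 2i had 273 and 472.

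With the line as fixed columns genotype counts leave out the spread between lines. They were 3336, 2462, 2408 and 2045 for knockout against wild type. AGP14 against knockout gave 3530 in serum and 4019 without LIF, and against wild type 3400 and 3804. LIF withdrawal gave 1215, 837 and 641 in wild type, knockout and AGP14, the interactions 1746 (serum with 2i), 3 (LIF) and 612 (MEK inhibitor), and MEK inhibitor against 2i 3875 and 3962. With the line as a random block, LIF withdrawal gave 755, 474 and 326 and the interactions 1217, 2 and 243. With the replicate number as a block, LIF withdrawal in AGP14 gave 103, the LIF interaction 1 and the MEK inhibitor interaction 64. That block also ended the feeder list call in serum (0.0547), gave one to the naive list with MEK inhibitor (0.0497) and one to Dnmt3l in the MEK inhibitor interaction, and changed no other call.

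Without the intensity trend, knockout against wild type in serum had 503 calls, AGP14 against wild type in serum 773, LIF withdrawal 170, 118 and 19, and the interactions of serum and of MEK inhibitor 325 and 20. With the mean of probe sets, knockout against wild type had 466 without LIF and 438 with MEK inhibitor, AGP14 against wild type in serum 844, and the interactions 301 and 21. With dim genes left out the MEK inhibitor interaction had 72. With an estimated correlation the signature medians of 0.40 and -0.31 in serum (both adjusted p = 0.0899), 0.27 and -0.12 without LIF (both 0.356) and 0.27 for the higher genes with MEK inhibitor (0.218) no longer passed. Among genes called at 2-fold or more, the turned shares were 72.4% (lower) and 72.3% (higher) for 2i followed in serum, 66.7% for higher in 2i without LIF, 71.9% for higher in serum, and 90.0% and 90.1% for lower and higher with MEK inhibitor followed in serum.

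Leaving out each array in turn, a lone array being assumed to vary like the other groups, gave these lowest and highest counts. Knockout against wild type had 727 to 1830 in 2i, 283 to 443 in serum, 291 to 594 without LIF and 334 to 624 with MEK inhibitor. AGP14 against knockout had 2858 to 3476, 882 to 1169 and 1290 to 1543, and against wild type 2807 to 4032, 153 to 1480 and 462 to 1972, in 2i, serum and serum without LIF. Serum against 2i had 4841 to 5539 in wild type, 5220 to 5446 in knockout and 1735 to 2481 in AGP14, and LIF withdrawal 35 to 364, 84 to 111 and 5 to 25. MEK inhibitor had 2973 to 4006 in wild type and 2940 to 3701 in knockout, and against 2i 1446 to 1687 and 1452 to 1881. The interactions had 224 to 542 (serum), 0 to 2 (LIF) and 20 to 44 (MEK inhibitor). EpiLC of day 2 had 5633 to 6145, of day 3 6167 to 6540, and day 3 against day 2 2042 to 2390. Signature medians ranged from 0.265 to 0.515 and from -0.47 to -0.175 in serum, from 0.145 to 0.395 and from -0.165 to -0.07 without LIF, and from -0.02 to 0.535 and from -0.425 to -0.21 with MEK inhibitor; without LIF and with MEK inhibitor 1 call each was lost.

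The share of turned genes ranged, for genes called in 2i and followed in serum, from 55.4% to 79.9% (lower) and 60.0% to 76.9% (higher), and followed without LIF from 61.3% to 80.9% and 55.2% to 67.1%. For genes called in serum it ranged from 89.4% to 97.2% and 74.0% to 86.9%, and for those called without LIF from 76.9% to 92.8% and 62.9% to 81.8%. For genes called with MEK inhibitor it ranged from 72.0% to 93.4% and 80.3% to 93.4% in serum, and from 79.5% to 92.8% and 70.6% to 85.7% without LIF.

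With different lines on both sides, wild-type replicate 2 in 2i and 1 in serum ended the signature call of the higher genes without LIF (0.065) and turned that of the lower genes (-0.025) and of the higher genes with MEK inhibitor (-0.0875). With knockout replicate 1 in the calls the turned shares moved to 61.7% (lower) and 61.8% (higher) for 2i followed in serum and 63.8% for lower in 2i followed without LIF. They moved to 84.8% and 74.2% for serum, 68.7% for higher without LIF, and 81.4% and 72.0% for MEK inhibitor followed without LIF. With knockout replicate 2 they moved to 69.8% and 73.1% for 2i in serum, 74.5% for lower in 2i without LIF, 81.3% and 66.7% for serum without LIF, and 80% and 78.1% for MEK inhibitor followed in serum.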

Other observations

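The tests of Y-linked genes were chosen after their values had been seen; those of imprinted genes as a class and of X-linked genes were written before.

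Some imprinted genes, expressed from a single parental allele, differed in the AGP14 arrays. Against knockout in serum, Nnat (-5.13), Mest (-2.49) and Sgce (-1.69) fell and Slc38a4 (4.86), Cobl (2.05), Plagl1 (1.60) and Ddc (0.83) rose. Without LIF the values were -5.99 for Nnat, -2.54 for Mest, 4.78 for Slc38a4 and 2.54 for Cobl. In the arrays labelled knockout against wild type in 2i, Sgce (2.66), Mirg (1.51) and Meg3 (0.76) rose, and Ddc fell in each medium (-1.08 in 2i, -0.91 in serum, -1.03 without LIF and -1.06 with MEK inhibitor).

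Whether imprinted genes as a class changed more often than other genes of like level was tested after the 7 genes already noticed had been taken out of the 56 measured. In AGP14 against knockout in serum, 8 of the 35 tested (22.9%) were called, against 15.7% of 10875 other genes (odds ratio 1.60, Fisher's exact test p = 0.243, and 0.639 after Benjamini-Hochberg adjustment over 4 comparisons). These other members are therefore not shown to be called more often, and the 95% interval of the odds ratio, 0.626 to 3.62, leaves the hypothesis open. Without LIF 6 of the 35 were called (17.1%, against 19.9% of the others).

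Replicate 1 of AGP14 had low levels of Y-linked transcripts in all 3 media. Eif2s3y lay at 4.50, 2.59 and 3.38 in 2i, serum and serum without LIF, against 9.80, 9.54 and 9.63 in replicate 2, and Uty at 2.92, 2.55 and 2.45 against 7.96, 8.40 and 8.67. The lowest level of these genes was 7.08 on wild-type arrays and 7.16 on knockout arrays. Loss of the Y chromosome in that culture stays open: the 6 pairs of gene and medium that could be compared, with a smallest fall of -5.04, are those in which the low levels were seen, and so do not test it. A line with a pair of active X chromosomes is argued against, since the median of 309 X-linked genes, replicate 1 minus replicate 2 and relative to autosomal genes, was at most -0.02 in size in the 3 media, and Xist lay at 5.80, 5.47 and 5.66 in replicate 1 and 5.53, 5.30 and 5.79 in replicate 2.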
